A study of Mus musculus with 24 samples.

How the data were processed

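Per the labels, RNA of GFP+ dermal fibroblasts and ItgA6+ epidermal keratinocytes, sorted from mouse back skin in 4 states, was amplified and hybridized to 24 Affymetrix arrays of 45101 probe sets, 3 arrays in each of 8 groups. The submitters' processing notes name RMA and MAS5, without versions and without saying which made which table. The deposited value table is in log2 units. On the linear scale the mean of each array, with 2% of the values trimmed at each end, is 100, the scaling MAS5 applies. Per the file headers, the authors' tables of regulated genes hold a linear ratio (fold change) with its direction for each pair of groups. The epidermal header gives an ANOVA p threshold and a minimum fold, and the dermal header gives none. Because the values were already log2, no pseudocount was added, and values below 0 were kept.

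Of 45101 probe sets 64 controls were left out and 45037 tested. Gene names came from the authors' tables, whose Entrez identifiers were looked up in a mouse symbol table (GRCm38.p6, used for names only): 7285 probe sets are listed there, 6480 with 1 gene, 267 with several and 538 with none, and 37752 others are unnamed here. Named are 4560 genes, 14.4% of the tested probe sets, and for a gene with several probe sets the one with the highest mean stands for it. Counts are of probe sets, a change from the plan of 1 value per gene made because most probe sets have no name.

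Groups, comparisons and all alternatives not marked here or below as added were chosen before the data were examined. Quantile normalization of the axis, the neonatal sets and the gene lists was added later. So was leaving out epidermal transient replicate 4 for gene lists and for contrasts that do not contain that array. The 12 arrays of a compartment were fitted together in limma 3.58.1 (R 4.3.3) with a mean per group and default eBayes, and contrasts were called at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets. Dermis against epidermis and the interactions used all 24 arrays. The labels number the mouse of each array. A number shared by the dermal and epidermal sorts of a state was taken as the same mouse, which holds for 11 numbers (neonatal dermis has 1, 2 and 3, neonatal epidermis 2, 3 and 4), and the mouse was also tried as a block. Pairing was checked on deviations from the group mean: 11 same-mouse pairs had correlations of -0.05 to 0.15 with a median of 0.02. Equal numbers in different states, taken as different mice, gave 0 to 0.05 over 13 dermal and -0.09 to 0.25 over 15 epidermal pairs.

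Gene lists were fixed beforehand from background knowledge and tested with camera at a correlation of 0.01 against the other named genes, adjusted over 26 lists per contrast, with fry and an estimated correlation as alternatives. Camera with all probe sets as background was added later, since unlisted probe sets have no names. Lists with under 5 named members (keratinocyte, T cell, endothelial, mast cell, melanocyte, skeletal muscle) had no list test, and no red cell or sex-linked gene was named. Members are also given adjusted over the list alone. Genes named in the text are list members, the largest named changes with no overlap between the arrays of the groups, or the gate and transgene genes; Ctnnb1, Krt14 and Pdgfra carry no name here. Results of some genes are not reported here.

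The neonatal axis projects each array on the difference of the neonatal and telogen means, and its groups were compared by an exact permutation test, whose smallest p with 3 against 3 arrays is 0.1. Overlaps between contrasts that share telogen arrays were set against 50 simulations with no real change. The group labels were also exchanged in all 10 splits of 3 against 3 arrays, or in 100 draws with the real grouping included.

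The pipeline was tested on simulated data with changes of 1, 2 and 4 log2 units given to 67, 67 and 66 of 45037 probe sets. Between sustained and telogen dermis 1.5%, 23.9% and 74.2% of them were called, with 5 false among 71 calls, and in epidermis 0%, 17.9% and 63.6%, with 0 false among 54. Dermis against epidermis found 32.8%, 76.1% and 100% (10 false of 149), and the interaction 1.5%, 4.5% and 66.7% (4 false of 52). Camera called the shifted list and 0 of the other 49 lists, and the axis gave 0.5 for a true 0.5. Changes of 1 log2 unit are thus mostly missed with 3 arrays per group.

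Array medians lay between 4.34 and 5.5 log2 units. Alternatives were quantile normalization, arrays centred on their median, dim probe sets left out, all 24 arrays or only the 6 compared, a replicate block, eBayes with trend and robust, array weights, a minimum log2 difference of 1, each array left out in turn, the authors' tables and, added after seeing the data, an offset of 16 before log2. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.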

Results

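The series title asks how activating beta-catenin in the epidermis reprograms the dermis. GFP+ dermal fibroblasts and ItgA6+ epidermal keratinocytes were sorted from mouse back skin in 4 states: neonatal wild type, adult telogen wild type, D2 with transient activation (anagen) and D2 with sustained activation (ectopic follicles). Each of the 8 groups has 3 arrays, 24 in all, and the 3 arrays of a group limit every estimate below. Differences are in log2 units, first-named state minus second, with the limma standard error after the sign ± and the Benjamini-Hochberg adjusted p over 45037 probe sets. D2 arrays differ from wild type telogen in genotype and activation together, so these are not told apart. The genes that carry names here were picked by the study on these same samples, so their changes are not independent evidence. Of 4560 named genes 2355, 85, 1700 and 477 were called in dermis and 1327, 173, 286 and 5 in epidermis. The order is neonatal, transient and sustained against telogen, then sustained against transient. Member counts of a list are to be read against these shares.

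The sorted compartments carry the genes of their cell types. Col1a2, a fibrillar collagen chain, averaged 12.35 in dermis and 8.76 in epidermis (3.59 ± 0.12, n = 12 per compartment, adjusted p = 1.07e-13). In neonatal epidermal arrays it stood at 11.07 to 11.36. Trp63, the transcription factor of basal keratinocytes, averaged 6.97 and 11.32 (-4.36 ± 0.14, adjusted p = 4.98e-14). Of 23 named collagen and matrix genes 22 were higher in dermis and 1 lower (camera adjusted p = 4.64e-10, adjusted p = 0.000632 with an estimated correlation), and all 8 named fibroblast genes were higher. All 13 macrophage genes but 1 were lower in dermis (12 lower, camera adjusted p = 6.13e-05, adjusted p = 0.0509 with an estimated correlation), as were 36 of 37 cell cycle genes (camera adjusted p = 6.76e-09, adjusted p = 0.058 with an estimated correlation). In total 18223 probe sets differed, 6448 higher in dermis and 11775 lower, and 15311 differed with the mouse as a block (the labels number the mice of each sort, and 11 numbers are shared by both sorts of a state). The share higher, 35.4%, was 47.5% with quantile normalization and 58.1% with arrays centred on their median.

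Itga6, the integrin used as the epidermal gate, averaged 5.93 in dermis and 9.89 in epidermis (-3.96 ± 0.16, adjusted p = 1.05e-12). In sustained dermis it rose from 4.5 to 7.18 (2.68 ± 0.41, adjusted p = 0.00403). Esr1, the estrogen receptor gene whose ligand-binding part the D2 fusion carries as background knowledge has it, rose in epidermis from 5.6 in telogen to 9.57 in transient (3.97 ± 0.57, adjusted p = 0.018) and 8.83 in sustained arrays (3.23 ± 0.57, adjusted p = 0.0299). Its probe set also reads the endogenous gene, which in dermis fell from 8.48 in telogen to 7.05 in sustained arrays (-1.43 ± 0.33, adjusted p = 0.0234) and 4.72 in neonatal arrays (-3.76 ± 0.33, adjusted p = 0.000118).

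Neonatal and telogen dermis set the scale for reprogramming. Neonatal fibroblasts carried far more Igf2, an imprinted growth factor (11.23 against 4.93, 6.3 ± 0.4, n = 3 per group, adjusted p = 3.27e-05), Ccna2, a mitotic cyclin (9.38 against 4.88, 4.5 ± 0.23, adjusted p = 1.85e-05), and Agtr2, an angiotensin receptor of fetal mesenchyme (9.03 against 0.78, 8.25 ± 0.61, adjusted p = 5.71e-05). The telogen dermal sort carried more Pcolce2, a procollagen processing enhancer (neonatal 4.69, telogen 11.78, -7.08 ± 0.34, adjusted p = 1.85e-05), the eosinophil chemokine Ccl11 (4.89 and 10.15, -5.26 ± 0.4, adjusted p = 6.1e-05) and the innate immune receptor Tlr4 (-1.32 and 8.68, adjusted p = 6.1e-05). The neonatal mean of Tlr4 lies below the 5th percentile of those arrays (-0.76 to -0.38), so no size is given for its difference. Where a mean lies near or below log2 3, as for Agtr2 in telogen, the signal is weak and the size of the difference is imprecise.

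Proliferation and imprinted growth genes were the neonatal side. Among all 4560 named genes 1068 were higher and 1287 lower in this contrast. Of 37 named cell cycle genes 35 were higher and 0 lower (36 higher adjusted over the list alone), with Cenpe, a mitotic kinesin, up by 5.2 ± 0.25 (camera adjusted p = 1.37e-13, adjusted p = 0.0724 with an estimated correlation). Imprinted genes were higher in 9 and lower in 1 of 16 (11 and 2 over the list alone; camera adjusted p = 0.0138, adjusted p = 0.124 with an estimated correlation), among them the cell cycle inhibitor Cdkn1c (3.28 ± 0.31). Follicle-inducing programmes were on the neonatal side too. Dermal papilla genes were higher in 10 and lower in 2 of 20 (13 and 2 over the list alone; camera adjusted p = 0.018, adjusted p = 0.527 with an estimated correlation). Hedgehog genes were higher in 7 and lower in 1 of 12 (8 and 1; camera adjusted p = 0.038, adjusted p = 0.362 with an estimated correlation). Wnt targets were higher in 7 and lower in 2 of 17 (10 and 2; camera adjusted p = 0.0446, adjusted p = 0.426 with an estimated correlation), and Notch genes in 4 and 0 of 6 (5 and 0; camera adjusted p = 0.0446, adjusted p = 0.426 with an estimated correlation). Examples are Hhip, a Hedgehog inhibitor that is itself a target (4.66 ± 0.52), and Dkk1, a secreted Wnt antagonist (5.08 ± 0.38).

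Immune genes were the telogen side. All 11 interferon response genes were lower in the neonatal dermal sort (11 over the list alone, camera adjusted p = 0.000508, adjusted p = 0.362 with an estimated correlation), including the GTPase Gbp2 (-6.45 ± 0.67) and the antiviral Mx1 (-3.72 ± 0.39). Chemokines and cytokines were lower in 7 and higher in 0 of 15 (10 lower over the list alone; camera adjusted p = 0.0393, adjusted p = 0.426 with an estimated correlation). Macrophage genes were lower in 4 and higher in 0 of 13 (6 lower over the list alone, camera adjusted p = 0.0945), with Csf1r at 4.03 against 9.36 (-5.33 ± 0.58, adjusted p = 0.000381). Whether more leukocytes in the telogen dermal sort account for part of these immune differences was not tested.

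In total 5994 probe sets were called between neonatal and telogen dermis, 3265 higher and 2729 lower (54.5% higher, 41.5% with arrays centred on their median), and 34.4% of probe sets had no overlap between the groups against 10% by chance. Only the 6 arrays compared gave 3879 calls. The median of all probe sets was 0.18. Leaving out neonatal replicate 1, 2 or 3 gave 3751, 3749 and 3912 calls.

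Transient activation asks what an anagen-like episode does to the dermis. Some genes of the dermal papilla, the fibroblast cluster that instructs the follicle, rose, with 5 of 20 past the threshold. Rspo2, a Wnt agonist, averaged 6.1 against -2.3 (n = 3 per group, adjusted p = 0.00522), where the telogen mean lies below the 5th percentile of those arrays (-0.96 to -0.9), so no size is given (16.2-fold in the authors' table). The papilla protease Corin rose from 2.47 to 8.21 (5.73 ± 0.56, adjusted p = 0.00523) and the chemokine receptor Cxcr4 from 7.33 to 10.89 (3.56 ± 0.32, adjusted p = 0.00522). Fmod, a collagen-binding proteoglycan, rose from 6.48 to 10.73 (4.25 ± 0.55, adjusted p = 0.016). Moxd1, a monooxygenase, fell from 8.34 to 5.11 (-3.23 ± 0.46, adjusted p = 0.0248). These calls rest on a spread estimated from all 12 dermal arrays: a limma fit of only the 6 arrays compared called 0 probe sets (4861 at an unadjusted p under 0.05).

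Papilla genes were higher in 5 and lower in 0 of 20 (14 and 1 adjusted over the list alone; camera adjusted p = 8.75e-08, adjusted p = 0.489 with an estimated correlation). Of 10 hair genes none passed over all probe sets and 6 were higher over the list alone (camera adjusted p = 0.00135, adjusted p = 0.139 with an estimated correlation). In the same dermal arrays the 36 probe sets most confined to epidermis rose by a median of 0.75, against 0.13 for all. Of 17 Wnt targets Wif1, a secreted antagonist, was higher (3.22 ± 0.55, adjusted p = 0.0424; not past the threshold with quantile normalization; 3 over the list alone; camera adjusted p = 0.035, adjusted p = 0.489 with an estimated correlation). Macrophage genes were lower as a list with 0 of 13 past either threshold (camera adjusted p = 0.0492, adjusted p = 0.318 with an estimated correlation). No gene of the cell cycle list passed: Ccna2 was 5.65 against 4.88 (0.77 ± 0.23, adjusted p = 0.183). Nuf2, a kinetochore gene outside that list, was lower at 0.15 against 3.26 (adjusted p = 0.0217). Igf2 at 6.4 against 4.93 did not pass either (1.47 ± 0.4, adjusted p = 0.151).

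In total 220 probe sets were called between transient and telogen dermis, 173 higher and 47 lower, and 18.6% had no overlap against 10% by chance. With trend and robust eBayes the calls numbered 1114. The share higher, 78.6%, was 67.5% with quantile normalization and 54.1% with arrays centred on their median, at a median of all probe sets of 0.13. Leaving out telogen replicate 2, 3 or 4 gave 52, 415 and 117 calls, and transient replicate 3 or 4 gave 71 and 66.

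With sustained activation papilla genes and proliferation genes were both higher than in telogen dermis. Rspo2 stood at 6.17 (adjusted p = 0.00054, 15.2-fold in the authors' table) and Cxcr4 at 11.59 (4.25 ± 0.32, adjusted p = 0.000343), each against telogen with n = 3 per group. Ccna2 rose from 4.88 to 7.91 (3.03 ± 0.23, adjusted p = 0.000343) and Cenpe from 2.74 to 6.89 (4.15 ± 0.25, adjusted p = 0.00026). Sod3, a secreted antioxidant enzyme, fell from 10.49 to 5.09 (-5.41 ± 0.84, adjusted p = 0.00431), the adipokine-like C1qtnf3 from 9.34 to 3.94 (-5.4 ± 0.72, adjusted p = 0.00238) and Dpp4, a surface peptidase of upper dermal fibroblasts, from 9.9 to 6.22 (-3.67 ± 0.37, adjusted p = 0.000852).

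Cell cycle genes were higher in 27 and lower in 0 of 37 (35 higher adjusted over the list alone; camera adjusted p = 2.16e-11, adjusted p = 0.12 with an estimated correlation). Papilla genes were higher in 13 and lower in 1 of 20 (15 and 1 over the list alone; camera adjusted p = 0.00025, adjusted p = 0.335 with an estimated correlation). For Hedgehog genes it was 9 and 2 of 12 (9 and 2; camera adjusted p = 0.0288, adjusted p = 0.274 with an estimated correlation). For Wnt targets it was 9 and 1 of 17 (13 and 2; camera adjusted p = 0.00488, adjusted p = 0.274 with an estimated correlation) and for Notch genes 2 and 0 of 6 (5 and 0; camera adjusted p = 0.0449, adjusted p = 0.335 with an estimated correlation). Lef1, the transcription factor that pairs with beta-catenin, rose from 6.51 to 8.6 (2.1 ± 0.35, adjusted p = 0.00648). Hair genes were higher in 8 and lower in 0 of 10 (9 and 1 over the list alone; camera adjusted p = 0.00378, adjusted p = 0.141 with an estimated correlation), with the inner root sheath keratin Krt25 at 8.29 against 2.81 (5.49 ± 0.83, adjusted p = 0.00387). Of 3 named keratinocyte genes Trp63 (2.39 ± 0.34, adjusted p = 0.00316) and Krt5, a basal keratin (2.13 ± 0.53, adjusted p = 0.0309), rose in the same dermal arrays.

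Immune and matrix-turnover genes fell. Interferon response genes were lower in 9 and higher in 0 of 11 (10 lower over the list alone; camera adjusted p = 0.000418, adjusted p = 0.274 with an estimated correlation), with the antiviral Ifit3 at 5.53 against 8.63 (-3.1 ± 0.41, adjusted p = 0.00218). Chemokines and cytokines were lower in 9 and higher in 0 of 15 (9 lower over the list alone; camera adjusted p = 0.0041, adjusted p = 0.274 with an estimated correlation), Ccl11 by -3.92 ± 0.4. Matrix enzymes were higher in 3 and lower in 12 of 18 (3 and 14; camera adjusted p = 0.00378, adjusted p = 0.274 with an estimated correlation), among them the stromelysin Mmp3 (-4.7 ± 0.53). Fn1, fibronectin, fell by 2.27 ± 0.21, a change its other probe sets did not carry past the threshold. The endothelial receptors Tek (-4.39 ± 0.51) and Kdr (-3.26 ± 0.76) and the macrophage receptor Csf1r (-4.43 ± 0.58) fell as well, all of them genes of other cell types.

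In total 4951 probe sets were called between sustained and telogen dermis, 3239 higher and 1712 lower, and 34.3% had no overlap against 10% by chance. Only the 6 arrays compared gave 2203 calls. The share higher, 65.4%, was 45.2% with quantile normalization and 26.3% with arrays centred on their median, at a median of all probe sets of 0.42, so the split rests on the scaling. Leaving out telogen replicate 4 gave 3008 calls and sustained replicate 2, 3 or 5 gave 2334, 3273 and 2783.

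The direct contrast of sustained and transient dermis asks what a longer signal adds. Proliferation genes were higher: Nuf2 rose from 0.15 to 5.66 (5.5 ± 0.43, n = 3 per group, adjusted p = 0.00159), the replication helicase Mcm5 from 5.63 to 8.66 (3.03 ± 0.3, adjusted p = 0.00351) and Ccna2 from 5.65 to 7.91 (2.26 ± 0.23, adjusted p = 0.00358). Tnxb, a matrix tenascin, fell from 10.29 to 6.16 (-4.13 ± 0.33, adjusted p = 0.00159), Ccl11 from 9.84 to 6.24 (-3.61 ± 0.4, adjusted p = 0.00426) and Mgp, a calcification inhibitor, from 9.45 to 6.03 (-3.43 ± 0.44, adjusted p = 0.00727). Papilla genes such as Tbx18 (8.26 against 6.88, adjusted p = 0.0593) did not pass. Genes of other cell types moved as well: Trp63 rose by 1.7 ± 0.34 (adjusted p = 0.0378; its other probe sets did not pass) and Tek fell by 3.13 ± 0.51 (adjusted p = 0.0175).

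Cell cycle genes were higher in 19 and lower in 0 of 37 (35 higher adjusted over the list alone; camera adjusted p = 5.47e-17, adjusted p = 0.0369 with an estimated correlation). Lower lists were interferon response with 4 of 11 (10 over the list alone; camera adjusted p = 0.000188, adjusted p = 0.365 with an estimated correlation), matrix enzymes with 4 of 18 (11; camera adjusted p = 0.000318, adjusted p = 0.365 with an estimated correlation) and chemokines with 5 of 15 (9; camera adjusted p = 0.000649, adjusted p = 0.365 with an estimated correlation). Collagen and matrix genes were higher in 1 and lower in 5 of 23 (1 and 8; camera adjusted p = 0.00394, adjusted p = 0.389 with an estimated correlation). BMP and TGF-beta genes were lower in 2 of 20 (6; camera adjusted p = 0.0346, adjusted p = 0.389 with an estimated correlation), such as Ltbp2, a latent TGF-beta binding protein (-2.7 ± 0.25).

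In total 999 probe sets were called between sustained and transient dermis, 527 higher and 472 lower, and 25.1% had no overlap against 10% by chance. A limma fit of only the 6 arrays compared called 0 (7307 at an unadjusted p under 0.05), and trend and robust eBayes 2617. The share higher, 52.8%, was 40% with quantile normalization and 32.1% with arrays centred on their median, at a median of all probe sets of 0.22. Leaving out transient replicate 2 or 3 gave 372 and 388 calls and sustained replicate 2, 3 or 5 gave 258, 561 and 354.

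**Figure D1:**
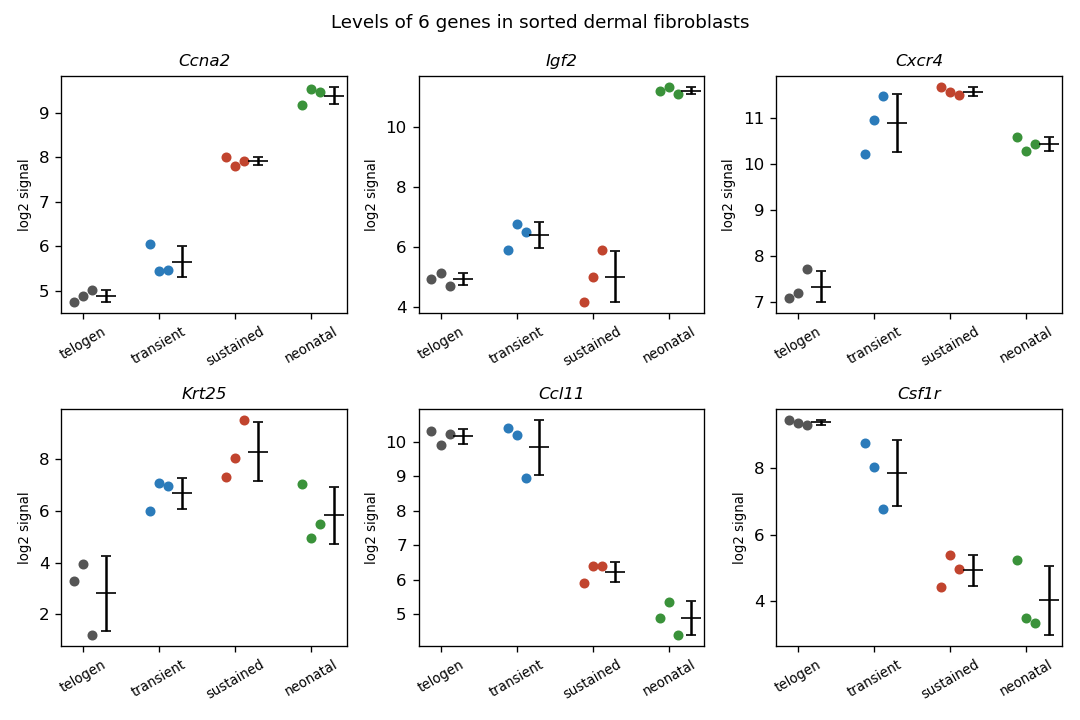
Log2 signal of 6 genes in dermal arrays of each state, a dot per array, with the mean and SD of 3 arrays as a black bar. Ccna2 lies at 4.88 in telogen, 5.65 in transient, 7.91 in sustained and 9.38 in neonatal arrays.

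How neonatal did the activated dermis become? Each array was placed on an axis with the mean of telogen at 0 and of neonatal at 1, over the 5994 probe sets called between them. Sustained dermis lay at 0.61 ± 0.04 and transient dermis at 0.28 ± 0.08 (SD, n = 3 per group), 0.33 apart (exact permutation p = 0.1, the smallest 3 against 3 arrays can give). Telogen arrays define both the axis and the comparison, and in simulation a group with no change lay at about 0.05. No such value was simulated for the single gene lists that follow. The position depended on the programme: cell cycle genes put sustained dermis at 0.74 ± 0.07 and transient dermis at 0.08 ± 0.03, and papilla genes at 1.1 ± 0.18 and 0.96 ± 0.22. Imprinted genes did not move toward the neonatal side, at 0.03 ± 0.08 and 0.04 ± 0.08, with Igf2 at 5.02 in sustained dermis against 11.23 in neonatal dermis. Against telogen, 3 of the 16 were lower in sustained dermis and 0 higher (camera adjusted p = 0.399), such as the noncoding RNA Meg3 (-1.39 ± 0.27, adjusted p = 0.0124).

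The contrast of sustained and transient dermis shares no array with neonatal against telogen. The 3265 probe sets higher in neonatal dermis had a median of 0.57 in it (camera p = 1.28e-13, p = 0.0068 with an estimated correlation) and the 2729 lower ones a median of -0.59 (camera p = 7.77e-46, p = 0.000269 with an estimated correlation), at a correlation of 0.34 between the contrasts and a covariance of 0.443. Ccna2 and Cenpe rose in it and Ccl11 fell, the directions of neonatal against telogen dermis. Without the cell cycle list the medians were 0.56 and -0.59. This leaves out only the named probe sets of 37 listed genes, and most probe sets carry no name. It therefore cannot show whether the shift is independent of proliferation.

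Of the sustained calls, 2634 were also called in neonatal dermis in the same direction, 53.2%, with 1539 higher and 1095 lower, and 23 in opposite directions. Lists of these lengths share 234.8 higher and 103.7 lower by n1 × n2/N. Part of the excess may come from the telogen arrays that both contrasts share: simulated contrasts with no real change shared 0 calls on average at the threshold and 1031.5 and 609 at the same list lengths, with a correlation of 0.5 and a covariance of 0.239 against 0.65 and 1.019 in the data. At an adjusted p under 0.01 the calls shared with sustained dermis numbered 907. Transient calls shared 144 in the same direction, 116 higher and 28 lower, against 12.5 and 2.8 by n1 × n2/N. The simulation gave 0 on average at the threshold and 103.7 and 31.4 at the same list lengths, with a correlation of 0.5 against 0.48 in the data and a covariance of 0.239 against 0.577. At an adjusted p under 0.01 the calls shared with transient dermis numbered 22. Cxcr4 and Hhip are among the genes higher in all 3 states than in telogen.

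**Figure D2:**
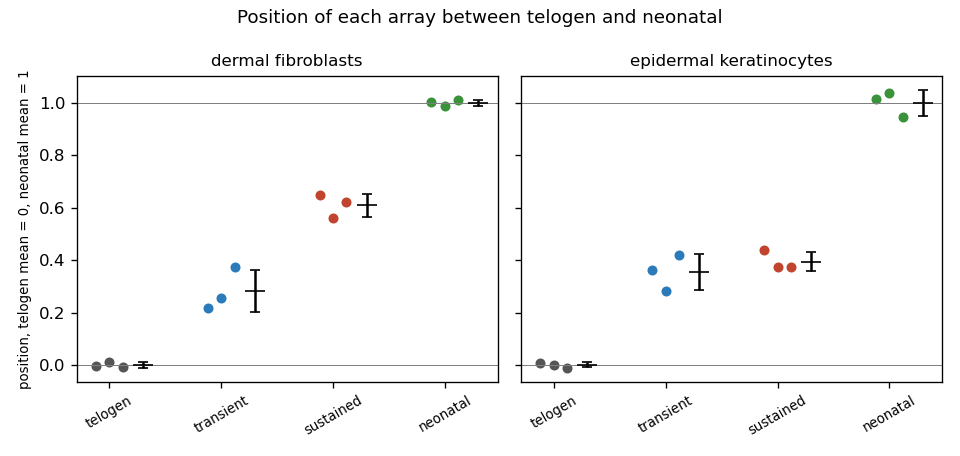
Position of each array on the telogen to neonatal axis, dermis and epidermis, a dot per array, with the mean and SD of 3 arrays as a black bar. Sustained dermis lies at 0.61 and transient dermis at 0.28, and the same epidermal states at 0.39 and 0.35.

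Neonatal and telogen epidermis differ in growth, follicle and immune genes. H19, an imprinted noncoding RNA, averaged 11.73 in neonatal and 2.64 in telogen arrays (9.09 ± 0.61, n = 3 per group, adjusted p = 0.000151) and Igf2 10.64 and 4 (6.64 ± 0.48, adjusted p = 0.000178). Col1a2 stood at 11.07 to 11.36 in the same neonatal arrays and at 9.57 to 10.13 in telogen ones. Whether fibroblasts in the neonatal epidermal sort carry part of the H19 and Igf2 signal was not tested. The hair keratin Krt25 was 8.01 and 1.92 (6.09 ± 0.98, adjusted p = 0.00686). Akr1c18, a steroid-metabolizing reductase, was -0.26 and 11.09 (adjusted p = 0.000248), and the alarmin Il33 4.12 and 9.45 (-5.32 ± 0.53, adjusted p = 0.000845). The neonatal mean of Akr1c18 lies among the 5th percentiles of those arrays (-0.82 to 0.38), so no size is given for its difference.

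Higher in neonatal epidermis were 29 and lower 0 of 37 cell cycle genes (35 higher adjusted over the list alone; camera adjusted p = 3.3e-12, adjusted p = 0.142 with an estimated correlation). So were 8 and 0 of 16 imprinted genes (12; camera adjusted p = 3.02e-05, adjusted p = 0.126 with an estimated correlation) and 8 and 0 of 10 hair genes (9 and 1; camera adjusted p = 9.49e-05, adjusted p = 0.142 with an estimated correlation). The same held for 5 and 1 of 12 Hedgehog genes (6 and 1; camera adjusted p = 0.0264, adjusted p = 0.184 with an estimated correlation) and 6 and 1 of 17 Wnt targets (8 and 2; camera adjusted p = 0.0359, adjusted p = 0.126 with an estimated correlation), with the morphogen Shh at 6.96 against 2.34 (4.62 ± 0.67, adjusted p = 0.00434). Genes of other cells were higher too, first collagen and matrix genes in 11 and 0 of 23 (14 and 1; camera adjusted p = 9.49e-05, adjusted p = 0.101 with an estimated correlation). So were fibroblast genes in 3 and 0 of 8 (5; camera adjusted p = 0.0264, adjusted p = 0.126 with an estimated correlation). Pericyte genes were higher in 3 and lower in 0 of 8 (4; camera adjusted p = 0.0167, adjusted p = 0.126 with an estimated correlation), with Rgs5, a pericyte signalling regulator, at 9.95 against 5.94 (4.01 ± 0.62).

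Lower in neonatal epidermis were 6 of 8 dissociation response genes (8 over the list alone; camera adjusted p = 0.00663, adjusted p = 0.184 with an estimated correlation), which include the immediate early Fos (-1.38 ± 0.3). Sebaceous genes were lower in 6 and higher in 0 of 10 (8 and 1; camera adjusted p = 0.0129, adjusted p = 0.126 with an estimated correlation), with the desaturase Scd1 at -2.7 ± 0.23. Bulge stem cell genes were higher in 1 and lower in 7 of 15 (2 and 7; camera adjusted p = 0.0471, adjusted p = 0.339 with an estimated correlation), with the surface marker Cd34 at -4.05 ± 0.47. Interferon response genes were lower in 3 of 11 (4; camera adjusted p = 0.0476, adjusted p = 0.142 with an estimated correlation).

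In total 3149 probe sets were called between neonatal and telogen epidermis, 1279 higher and 1870 lower (40.6% higher, 57.3% with arrays centred on their median), and 32.6% had no overlap against 10% by chance. With trend and robust eBayes the calls numbered 5187. Leaving out neonatal replicate 2 or 3 gave 1624 and 1587 calls and telogen replicate 2, 3 or 4 gave 1353, 1386 and 1545.

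Genes of the hair shaft and its sheath were higher in transient than in telogen epidermis. Krtap8-1, a hair shaft protein, averaged 7.26 against -1.41 (n = 3 per group, adjusted p = 2.66e-05, 16.1-fold in the authors' table) and Fgf5, the growth factor that ends anagen, 7.46 against -0.76 (adjusted p = 0.00424, 26.9-fold in the authors' table). Both telogen means lie below the 5th percentile of those arrays (-0.66 to -0.33), so no size is given for these differences. Krt25 rose from 1.92 to 9.02 (7.1 ± 0.98, adjusted p = 0.0162). Tnc, a matrix protein of remodelling tissue, rose from 6.54 to 10.27 (3.74 ± 0.27, adjusted p = 0.00105) and Shh from 2.34 to 6.47 (4.12 ± 0.67, adjusted p = 0.0281). Col1a2, a fibroblast gene, fell from 9.8 to 6.84 (-2.96 ± 0.32, adjusted p = 0.00633), and whether the sort held fewer fibroblasts was not tested. Axin2, a feedback target of beta-catenin, fell from 8.42 to 7.05 (-1.37 ± 0.24, adjusted p = 0.0361).

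Hair genes were higher in 7 and lower in 0 of 10 (9 and 1 adjusted over the list alone; camera adjusted p = 5.75e-08, adjusted p = 0.226 with an estimated correlation), and papilla genes in 1 of 20 (4; camera adjusted p = 0.0416, adjusted p = 0.226 with an estimated correlation). Other follicle lists did not pass: Hedgehog genes were higher in 1 of 12 (camera adjusted p = 0.0524), Wnt targets higher in 1 and lower in 1 of 17 (0.521), and bulge stem cell genes higher in 0 and lower in 1 of 15 (0.6). Cell cycle genes were higher as a list with 0 of 37 past either threshold (camera adjusted p = 0.0105, adjusted p = 0.574 with an estimated correlation). Macrophage genes were lower in 2 of 13 (11; camera adjusted p = 4.54e-06, adjusted p = 0.321 with an estimated correlation), including the immune adaptor Tyrobp (-2.41 ± 0.43, adjusted p = 0.0378). Langerhans cell genes were lower in 0 of 5 (5; camera adjusted p = 0.0078, adjusted p = 0.354 with an estimated correlation) and fibroblast genes in 2 of 8 (4 lower and 1 higher; camera adjusted p = 0.0416, adjusted p = 0.226 with an estimated correlation).

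In total 380 probe sets were called between transient and telogen epidermis, 305 higher and 75 lower, and 26.1% had no overlap against 10% by chance. Only the 6 arrays compared gave 15 calls, 15 higher and 0 lower, and trend and robust eBayes 1479. The share higher, 80.3%, was 70.1% with quantile normalization, at a median of all probe sets of 0.18. It was 57.5% without dim probe sets and 58.4% with an offset of 16 before log2. Leaving out telogen replicate 2, 3 or 4 gave 67, 96 and 67 calls and transient replicate 2 or 4 gave 176 and 162.

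Sustained activation went with higher hair and Hedgehog genes and lower immune genes than in telogen epidermis. With an estimated correlation 0 of 26 lists passed in this contrast. Krtap8-1 stood at 7.17 (against telogen with n = 3 per group, adjusted p = 2.97e-05, 17.9-fold in the authors' table), Shh at 7.07 (4.73 ± 0.67, adjusted p = 0.013), and the Hedgehog effector Gli1 rose from 5.27 to 8.13 (2.86 ± 0.42, adjusted p = 0.014). H2-Aa, an antigen-presenting class II chain, fell from 10.14 to 6.09 (-4.05 ± 0.53, adjusted p = 0.0104), Il33 from 9.45 to 5.68 (-3.77 ± 0.53, adjusted p = 0.0132) and Cd209a, a dendritic cell lectin, from 7.34 to 1.14 (-6.2 ± 0.7, adjusted p = 0.00602). Krt1, a keratin of differentiating layers, fell from 9.08 to 5.49 (-3.59 ± 0.66, adjusted p = 0.0347), and did not pass with quantile normalization.

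Hair genes were higher in 7 and lower in 0 of 10 (9 and 1 adjusted over the list alone; camera adjusted p = 1.92e-07, adjusted p = 0.104 with an estimated correlation). Hedgehog genes rose in 6 and fell in 0 of 12 (7; camera adjusted p = 0.00032, adjusted p = 0.104 with an estimated correlation). Papilla genes rose in 4 and fell in 1 of 20 (8 and 1; camera adjusted p = 0.0164, adjusted p = 0.104 with an estimated correlation), and Wnt targets in 2 and 0 of 17 (7 and 1; camera adjusted p = 0.0464, adjusted p = 0.105 with an estimated correlation). Also higher as lists were upper dermal genes with 2 of 12 (5; camera adjusted p = 0.0294, adjusted p = 0.105 with an estimated correlation) and pericyte genes with 0 of 8 (2; camera adjusted p = 0.0464, adjusted p = 0.105 with an estimated correlation). Cell cycle genes were higher as a list with 0 of 37 past either threshold (camera adjusted p = 1.35e-07, adjusted p = 0.191 with an estimated correlation).

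Macrophage genes were lower in 8 and higher in 0 of 13 (13 lower over the list alone; camera adjusted p = 9.62e-10, adjusted p = 0.104 with an estimated correlation), with the Fc receptor chain Fcer1g at -2.97 ± 0.32 (adjusted p = 0.00545). Langerhans cell genes were lower in 4 of 5 (5; camera adjusted p = 5.23e-05, adjusted p = 0.105 with an estimated correlation). Chemokines were lower in 4 of 15 (9; camera adjusted p = 0.001, adjusted p = 0.104 with an estimated correlation) and Schwann cell genes in 1 of 5 (2; camera adjusted p = 0.0384, adjusted p = 0.105 with an estimated correlation).

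In total 516 probe sets were called between sustained and telogen epidermis, 281 higher and 235 lower (54.5% higher, 42.3% with arrays centred on their median), at a median of all probe sets of 0.14, and 23.7% had no overlap against 10% by chance. Only the 6 arrays compared gave 217 calls, and trend and robust eBayes 1229. Leaving out telogen replicate 2, 3 or 4 gave 89, 130 and 139 calls and sustained replicate 2, 3 or 5 gave 80, 232 and 229.

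**Figure D3:**
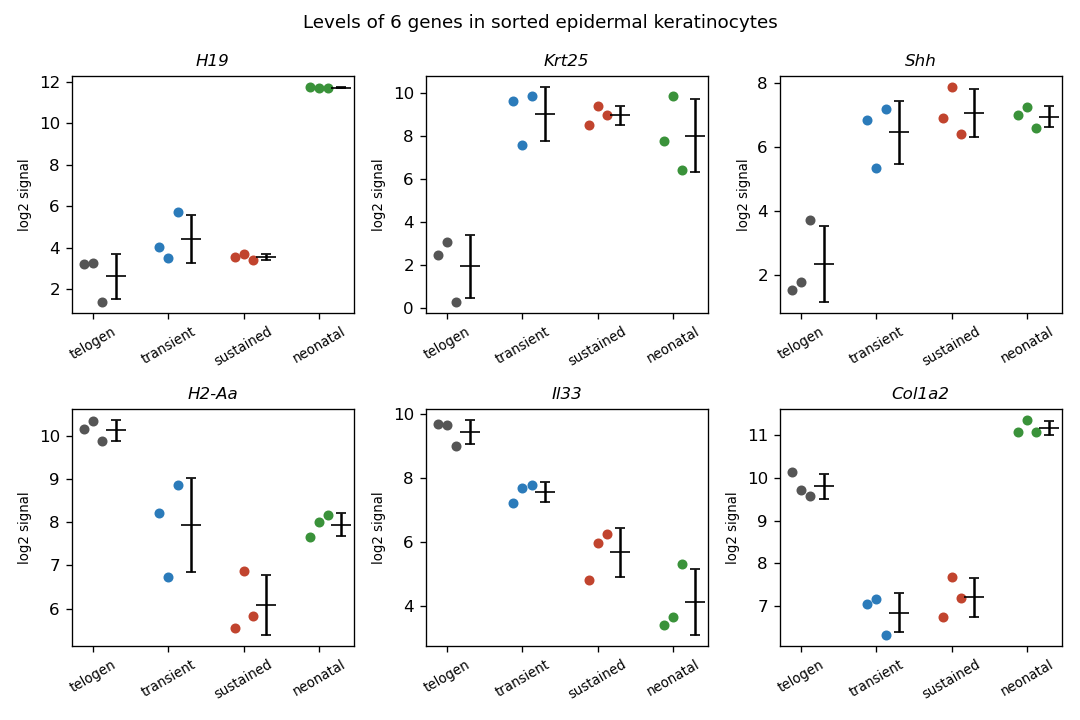
Log2 signal of 6 genes in epidermal arrays of each state, a dot per array, with the mean and SD of 3 arrays as a black bar. H2-Aa lies at 10.14 in telogen, 7.94 in transient, 6.09 in sustained and 7.94 in neonatal arrays.

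Few single genes were called between sustained and transient epidermis, 7 probe sets here and 173 with trend and robust eBayes. Col27a1, a fibrillar collagen, was higher in sustained arrays (8.38 against 5.14, 3.24 ± 0.34, n = 3 per group, adjusted p = 0.0211; its other probe sets did not pass) and S100a9, a neutrophil alarmin, lower (1.05 against 5.53, -4.48 ± 0.38, adjusted p = 0.00488). Gli1 at 8.13 against 5.33 did not pass (2.8 ± 0.42, adjusted p = 0.0845). Lists that were lower with 0 members past the threshold were macrophage (7 of 13 over the list alone; camera adjusted p = 0.000191, adjusted p = 0.263 with an estimated correlation) and chemokine genes (6 of 15; camera adjusted p = 0.00175, adjusted p = 0.263 with an estimated correlation). The same held for Langerhans cell (4 of 5; camera adjusted p = 0.00258, adjusted p = 0.263 with an estimated correlation) and Schwann cell genes (3 of 5; camera adjusted p = 0.036, adjusted p = 0.263 with an estimated correlation). Higher with 0 members past it were cell cycle (1 of 37; camera adjusted p = 0.00101, adjusted p = 0.539 with an estimated correlation) and Hedgehog genes (4 of 12; camera adjusted p = 0.00456, adjusted p = 0.263 with an estimated correlation).

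In total 7 probe sets were called between sustained and transient epidermis, 3 higher and 4 lower, with 4215 at an unadjusted p under 0.05 and 13.7% without overlap against 10% by chance. The count was 106 with an offset of 16 before log2, 81 without dim probe sets and 1 from only the 6 arrays compared, and the authors' table lists 325, so 7 calls do not bound how many genes differ. The share higher, 42.9%, was 65.5% with quantile normalization and 62.5% with arrays centred on their median. Leaving out transient replicate 3 gave 4 calls and sustained replicate 2 or 3 gave 3 and 12.

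On the axis of the 3149 epidermal probe sets, sustained arrays lay at 0.39 ± 0.04 and transient arrays at 0.35 ± 0.07 (SD, n = 3 per group), 0.04 apart (exact permutation p = 0.4). Imprinted genes such as H19 and Igf2 were again near telogen, at 0.04 in sustained and 0.14 in transient arrays, while hair genes such as Krt25 reached 1.1 and 1.08. Whether fibroblasts in the neonatal epidermal sort set part of this imprinted axis was not tested. In sustained against transient epidermis the probe sets higher in neonatal epidermis had a median of 0.03 (camera p = 0.0372, p = 0.379 with an estimated correlation) and those lower a median of -0.08 (camera p = 0.509). The contrasts had a correlation of -0.07.

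Shared calls with neonatal epidermis in the same direction numbered 260 for sustained (155 higher and 105 lower) and 171 for transient arrays (143 and 28). By n1 × n2/N they would be 8 and 9.8, and 8.7 and 3.1. How much of the excess comes from the shared telogen arrays is left open. With no real change the simulation gave 0 on average at the threshold and, at the same list lengths, 112.3 and 112.1, and 119.3 and 43.1. Its correlation was 0.5 against 0.51 and 0.49 in the data, and its covariance 0.256 against 0.557 and 0.625. At an adjusted p under 0.01 the shared calls numbered 33 for sustained and 20 for transient arrays. Krt25, Shh and Tnc were higher in all 3 states than in telogen.

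Did the compartments respond differently? The change of a state against telogen in dermis minus that in epidermis was called for 2555 probe sets in neonatal skin, 1413 higher and 1142 lower, for 446 in transient (213 and 233) and for 1248 in sustained skin (718 and 530). With the mouse as a block these were 709, 19 and 358. Sustained against transient gave 323 (179 and 144), and 24 with the block. With sustained activation Ccna2 rose by 2.34 ± 0.42 more in dermis than in epidermis (n = 3 per group, adjusted p = 0.00418), and the cell cycle list changed more there in 12 of 37 genes (20 over the list alone; camera adjusted p = 9.83e-08, adjusted p = 0.125 with an estimated correlation). Col1a2 changed by 2.36 ± 0.35 more in sustained dermis (adjusted p = 0.000983) and by 3.02 ± 0.35 more in transient dermis (adjusted p = 0.00139), since it fell in the epidermal sort and not in the dermal one. In epidermal arrays it lay at 9.57 to 10.13 in telogen, 6.32 to 7.17 in transient and 6.75 to 7.67 in sustained skin. Whether fewer fibroblasts in the D2 epidermal sorts account for this fall was not tested. The change of Ccl11 in sustained skin differed by -4.08 ± 0.9 (adjusted p = 0.0182), with -3.92 in dermis and 0.16 in epidermis. That of Lgr5, a stem cell receptor, in neonatal skin differed by 6.2 ± 0.66 (adjusted p = 2.3e-05), with 4.77 in dermis and -1.43 in epidermis.

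The share higher among these interaction calls was 55.3% for neonatal skin (30.9% with arrays centred on their median), 47.8% for transient (35.5%), 57.5% for sustained (32.1%, and 47.2% with quantile normalization) and 55.4% for sustained against transient (35.3%, and 40.7%). For transient skin, with 446 calls, leaving out dermal telogen replicate 2, 3 or 4 gave 289, 928 and 236, epidermal telogen replicate 2, 3 or 4 gave 273, 256 and 216, dermal transient replicate 3 or 4 gave 270 and 261, and epidermal transient replicate 4 gave 270. For sustained skin, with 1248, epidermal telogen replicate 4 gave 819, dermal sustained replicate 2 gave 806 and epidermal sustained replicate 2 gave 829. For sustained against transient skin, with 323, dermal transient replicate 3 or 4 gave 200 and 531, epidermal transient replicate 4 gave 209, dermal sustained replicate 2 or 5 gave 158 and 197, and epidermal sustained replicate 3 gave 173.

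Some lists did not pass in any state contrast within a compartment. The lowest camera adjusted p was 0.0692 for adipocyte genes (neonatal epidermis, Dgat2 lower by -2.06 ± 0.29), 0.0794 for lower dermal and adipogenic genes (sustained dermis, Gsn -1.14 ± 0.21), 0.0798 for epidermal differentiation genes (sustained epidermis, with Krt1), 0.0899 for Wnt ligands, receptors and antagonists (transient dermis, with Rspo2) and 0.137 for wound keratins and alarmins (sustained epidermis, with S100a9). Lists with under 5 named genes had no list test. Among T cell genes 2 of 3 were lower in neonatal epidermis (Cd3g, a T cell receptor chain, -4.99 ± 0.98, adjusted p = 0.0157), among melanocyte genes the transcription factor Mitf was lower there (-2.38 ± 0.27, adjusted p = 0.00166; its other probe sets did not pass) and Sox10 higher (2.29 ± 0.36, adjusted p = 0.00645). The mast cell gene Kit did not pass in any of these contrasts, and of 2 muscle genes the troponin Tnnt3 was lower in sustained dermis (-1.79 ± 0.24, adjusted p = 0.00229).

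Array quality differed between groups. The Gapdh 3' minus 5' difference, a sign of RNA length, was 4.12 ± 1.09 in dermal telogen arrays (4.97, 2.9 and 4.5 for replicates 2, 3 and 4; SD, n = 3) and 2.92 to 3.23 in the other dermal groups. Telogen replicate 3, with a Gapdh difference among those of the other dermal groups, had Ccna2 at 4.88 and Igf2 at 5.13. Replicates 2 and 4 had Ccna2 at 4.74 and 5.01 and Igf2 at 4.94 and 4.72. Ccna2 and Igf2 alone do not show whether RNA length bears on the calls, and that was not tested. With all arrays transient, neonatal and sustained dermis against telogen gave 220, 5994 and 4951 calls. Without telogen replicate 3 they gave 415, 5839 and 4537, more than without replicate 2 (52, 4144 and 3351) or 4 (117, 4225 and 3008). Replicate 4 of transient epidermis stood apart from its group, with a mean correlation of 0.82 and a lower quartile of 4.14.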

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

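These results were drawn out by a difference between the compartments. The tests of epidermal carry-over, scaling and background below were chosen after the results were seen, while the exchange of group labels was chosen before. The change of a state in dermis minus that in epidermis was called for 2555 probe sets (neonatal against telogen), 446 (transient against telogen), 1248 (sustained against telogen) and 323 (sustained against transient). With the labels of the 2 states compared exchanged within each compartment, the real count was matched or passed in 1, 1, 4 and 5 of 100 draws, the real one included, and the highest other counts were 2258, 185, 1831 and 1315. For 323 chance is not excluded. Draws with several times that count point to structure among the arrays, since a draw that leaves the grouping of a compartment whole still carries its change of state, so these draws are not a clean null for an interaction.

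In neonatal against telogen skin the change differed between compartments for the lists of cell cycle (camera adjusted p = 8.72e-07, 0.11 with an estimated correlation), collagens and matrix proteins (0.00201, 0.0587), matrix enzymes (0.00201, 0.0587), bulge and stem cells (0.00234, 0.0874), interferon response (0.00427, 0.145), fibroblast (0.0116, 0.0587) and upper dermal genes (0.0421, 0.0874). In sustained against telogen skin it differed for cell cycle (9.83e-08, 0.125), matrix enzymes (0.000553, 0.0858), interferon response (0.0175, 0.291), wound keratins and alarmins (0.0175, 0.0968) and macrophage genes (0.0284, 0.341). In sustained against transient skin it differed for cell cycle (7.37e-14, 0.0718), BMP and TGF-beta (0.00175, 0.1), interferon response (0.00602, 0.12), matrix enzymes (0.0112, 0.1) and collagens (0.0144, 0.1).

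Hair, keratinocyte and cell cycle genes were higher in sustained than in telogen dermis, and epidermal cells in the dermal sort may account for part of it. The 36 probe sets most confined to epidermis rose by a median of 1.93 log2 units against 0.42 for all, with 16 called higher and 0 lower. In transient dermis they rose by 0.75 against 0.13. For each gene the rise in linear signal from telogen to sustained dermis was taken as a share of its sustained epidermal level. The median share of the 36 was 7.92%, with 5th and 95th percentiles of 3.72% and 24.6%. Krt17, from the wound keratin list, and the keratinocyte genes Krt5 and Trp63 had shares of 8.76% to 18.7% (median 12.4%), each inside that range. They are themselves among the 36, so lying inside it was partly fixed in advance. Among the other 33 their median share lay at percentile 81.8, which leaves carry-over open for them. All 27 called cell cycle genes lay above that range (100%, median 52%), and so did the hair genes by their median of 53.8% (percentile 100; 87.5% stayed called with quantile normalization) except Shh at 13.3%, with Lef1 also a papilla gene, so the same carry-over is not the whole cause of either. Follicle cells that lack ItgA6 in the dermal sort, and expression by the dermal cells, were not tested.

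Leukocyte markers were lower in sustained than in telogen epidermis. Bright markers were those with a telogen level of 6 or more. Of these 16, 15 (93.8%) held their median difference of -3.07 log2 units within 2 standard errors, all but Cd52. Fewer leukocytes among the sorted cells would give this. The cut and the test were chosen after the results were seen, and standard errors of up to 1.06 make it a weak test. Of the dimmer markers Cd7 held that median, and C1qc (-6.47 ± 0.94) and Adgre1 (-1.74 ± 0.52) did not. All 10 markers called among the 19, bright or dim and with C1qc among them, stayed called with quantile normalization, 100%, so scaling is excluded. Lower expression per cell was not tested and would need cells counted.

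More probe sets were higher than lower in sustained dermis, 65.4%, while the authors' table lists 1130 up and 1872 down, controls included. With quantile normalization the share was 45.2%, so the scaling of the arrays can account for the excess. Among calls at or above the median level it was 52.1%, against 86.3% below it, which does not separate background from a real change of weak genes. A biological excess of higher genes is not shown here.

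Within a compartment the real grouping gave the highest count in each contrast, 1 of 10 splits, too few to put a share under 0.05 on it. The highest other counts for neonatal, transient and sustained against telogen and for sustained against transient were 4, 4, 2 and 1 in dermis and 1, 2, 0 and 5 in epidermis. Between dermis and epidermis 1 of 100 draws reached 18223, the real one, and the highest other gave 7128.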

How the results depend on the processing

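Counts of calls moved with the processing, and so did the balance of higher and lower calls: with arrays centred on their median sustained dermis gave 5218 calls, 26.3% higher against 65.4%, and dermis against epidermis 16007, 58.1% against 35.4%. Where no cause is named the cause was not tested. Counts not printed stayed within a factor of 1.5.

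With the replicate number as a block within a compartment, the counts for neonatal, transient and sustained against telogen and sustained against transient were 1826, 0, 837 and 1 in dermis and 1518, 103, 9 and 0 in epidermis. Numbers are not shared mice across states, and the block takes away degrees of freedom. The limma counts of 0 stood beside 5388 (transient dermis) and 3324 (sustained against transient epidermis) at an unadjusted p under 0.05. With the mouse as a block the interactions, in the same order, gave 709, 19, 358 and 24. From only the 6 arrays compared, dermis gave 3879, 0, 2203 and 0, and transient and sustained against telogen and against each other in epidermis 15, 217 and 1, with fewer residual degrees of freedom. From all 24 arrays transient dermis gave 624 and sustained against transient dermis 1662, and the epidermal contrasts 1155 (transient), 804 (sustained) and 29 (sustained against transient).

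Leaving out dim probe sets gave 815 calls in transient dermis, 2057 in sustained against transient dermis, 854, 1012 and 81 in the epidermal contrasts of transient, sustained and both, and 1085 (transient) and 644 (sustained against transient) in the interactions, with fewer probe sets tested. With trend and robust eBayes the counts were 1114 and 2617 in those dermal contrasts, 5187, 1479, 1229 and 173 in the 4 epidermal ones, and 1176 and 755 in the interactions. Array weights gave 107 for transient dermis and 5237 and 1071 for neonatal and sustained epidermis. An offset of 16, which damps weak signals, gave 863, 7544 and 2928 in transient, sustained and sustained against transient dermis, 4824, 1079, 1116 and 106 in the epidermal contrasts and 3921, 1437, 2456 and 1029 in the interactions. Quantile normalization gave 123 in transient dermis and 29 in sustained against transient epidermis, and centring on the median 133 in transient dermis and 228 in transient epidermis. At a log2 difference of at least 1, dermis and epidermis differed in 10178.

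With control probe sets left out, the authors' tables list 3912, 764, 2978 and 1563 in dermis and 2021, 972, 1045 and 325 in epidermis. Those also called here in the same direction are 3424, 143, 2278 and 681, and 1543, 229, 388 and 3.

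At an adjusted p under 0.01 the calls shared with neonatal skin were 907 (sustained) and 22 (transient) in dermis and 33 and 20 in epidermis. Over all probe sets the epidermal axis difference of 0.04 became -0.05. The probe sets higher in neonatal epidermis lost their shift in sustained against transient epidermis with an estimated correlation (0.03, p = 0.379), without the cell cycle list (0.02, p = 0.064) and with quantile normalization (0.07, p = 0.111).

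Lists called numbered 8, 4, 9 and 6 in dermis and 12, 6, 11 and 6 in epidermis. An estimated correlation left 0, 0, 0 and 1, and 0, 0, 0 and 0. Fry called 23, 7, 18 and 14 in dermis and 23 and 19 in neonatal and sustained epidermis. Against all probe sets 15, 17 and 15 were called in neonatal, sustained and sustained against transient dermis and 19 and 17 in neonatal and sustained epidermis. In neonatal dermis 4 were called among bright genes and 3 with the offset of 16. Of the 62 calls quantile normalization kept 57, the replicate block 60 and the bright genes 48 of 61, and no list turned direction.

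Among named genes called, quantile normalization kept 441 of 466, the offset 456 and the replicate block 207, and leaving out an array kept 2255 of 2947 values. The other probe sets of a gene were judged by their mean difference and the smallest adjusted p among them, so they need not all pass. By this rule they kept 131 of 173 and turned 4: Laptm5 in dermis (0.31 for neonatal, 1.97 for sustained, 1.02 for sustained against transient) and Cxcl12 in sustained dermis (0.63).

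Leaving out each array in turn, which also removes samples, gave these ranges. In dermis they were 3749 to 5839 (neonatal), 52 to 415 (transient), 2334 to 4537 (sustained) and 258 to 1244 (sustained against transient), and in epidermis 1353 to 3946, 67 to 382, 80 to 679 and 3 to 12. The 3946 and 679 come from leaving out transient replicate 4, an array of neither contrast. Leaving out an array of these 2 contrasts gave at most 2291 and 232, below the 3149 and 516 of the main fit. Between dermis and epidermis the range was 17057 to 18081, and for the interactions 1847 to 2699, 216 to 928, 806 to 1307 and 158 to 531. The axis difference was 0.29 to 0.38 in dermis and -0.01 to 0.08 in epidermis, negative without transient replicate 3. The neonatal sets had medians of 0.45 to 0.72 and -0.75 to -0.55 in dermis and -0.09 to 0.13 and -0.13 to 0.01 in epidermis. Without epidermal transient replicate 4, 10 lists were called in neonatal epidermis, 11 in sustained, 7 in sustained against transient and 5 in transient.

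Weak signals limit the split of sustained dermal calls: 86.3% were higher below the median level, 1664 of 1929, and 1575 of 3022 above it, and whether background or a real change of weak genes makes that difference is left open.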

Other observations

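The test of the hypothesis here was chosen after the results were seen. The sustained dermal sort lay toward the neonatal state in some programmes and not in others. Genotype and activation are not told apart in it. Genes of other cell types moved too: Csf1r, Tek and Kdr fell and Trp63 and Krt5 rose. Macrophage genes lay at 0.69 and pericyte genes at 1.14, so a changed mix of sorted cells is left open. Cell cycle genes reached 0.74 of the way from telogen to neonatal dermis, Hedgehog genes 1.12, Wnt targets 0.86, interferon response genes 0.63 and chemokines 0.71. Imprinted growth genes reached 0.03, with 3 of 16 lower than in telogen and 0 higher, and with Igf2 at 5.02 against 11.23 in neonatal dermis and Cdkn1c and Peg3 among the genes high in neonatal dermis only. Other lists also lay near telogen in sustained dermis, with epidermal differentiation genes at 0.06, Schwann cell genes at 0.18 and adipocyte genes at 0.29. Transient activation gave 0.08 for cell cycle, 0.13 for interferon response, 0.16 for chemokines, 0.42 for Wnt targets, 0.71 for Hedgehog and 0.96 for papilla genes.

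The hypothesis was that sustained dermis is shifted on the log2 scale by the same share in every gene list. It predicts a position of the imprinted list near the 0.61 of all called probe sets, and the position was 0.03, away from that prediction. The list was picked after the positions were seen, so this restates the result and is not an independent test. A mixture with cells neonatal in every list would move log2 values by unequal shares. It would still raise genes far higher in neonatal dermis. Against telogen, 9 of 16 imprinted genes were higher in neonatal dermis, and 0 higher and 3 lower in sustained dermis. Igf2 lay at 4.18 to 5.89 in sustained, 4.72 to 5.13 in telogen and 11.13 to 11.36 in neonatal arrays. With the list at 0.03 ± 0.08 (SD, n = 3), these values argue against such a mixture, for the imprinted genes. Cells neonatal-like only in other lists were not tested, and cells were not counted.

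On the epidermal axis Langerhans cell genes lay at 1.89 for sustained and 0.99 for transient arrays. Interactions of single genes included Csf1r, a macrophage receptor, whose change in neonatal dermis minus that in neonatal epidermis was -6.53 ± 0.95 (adjusted p = 0.000439; -5.33 in dermis, 1.2 in epidermis), Tnc, which rose less in transient dermis than in epidermis (-2.8 ± 0.33, adjusted p = 0.00139), and Trp63, which rose more in sustained dermis (2.15 ± 0.39, adjusted p = 0.00439).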
